A study of Mus musculus with 8 samples.

How the data were processed

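Total RNA from the middle colon of 8 DSS-treated mice, 4 wild type and 4 Trim58 knockout, was hybridised to 1 Affymetrix whole-transcript array per mouse. Per the labels' protocols, 200 ng of RNA per sample was amplified and labelled with biotin with the WT PLUS kit. The labels name separate mice, so the replicates are biological. The deposited values are on the log2 scale, and per the submitters' processing notes the authors made them by RMA in Affymetrix Expression Console 1.4. RMA corrects background, sets the arrays to a common distribution and summarises the probes of a probe set as a log2 value. A filter on probe sets and a scan date or batch are not given in the sources used here, and raw scanner files were not analysed here. RMA compresses large differences near background and near saturation, so folds of dim or very bright genes are understated. Arrays give signal, not counts, so no sequencing depth applies.

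The table held 41345 probe sets. In the platform annotation 23521 of them carried 1 gene symbol, 1814 several and 16010 none. Symbols were looked up by Entrez identifier in the reference gene table (assembly GRCm38.p6), which held 23328 of the single-symbol probe sets. Only probe sets with 1 symbol were tested, and where a gene had several (1082 genes) the one with the highest mean over all 8 arrays was used, leaving 22180 genes. No filter on dim genes was applied. The values were used as deposited without further normalization.

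Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. A second count used an unadjusted p under 0.05 and at least 1.5-fold. Fold values are 2 to the power of the log2 difference. Trim58 and the list means were also tested by exact two-sided permutation over the 70 assignments of 4 of 8 arrays. 28 gene lists for pathways and cell types were tested with limma's camera with a preset correlation of 0.01. Camera with an estimated correlation, camera on ranks and fry were alternatives, and adjustment was over the 28 lists. For each list the genes past 0.05 are also counted after Benjamini-Hochberg adjustment over the list alone. 498 of the 544 list entries were measured.

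The tests, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took Trim58, the 10 largest differences in each direction among genes past the adjusted threshold with no overlap between genotypes, and 3 members with the smallest p from each list that passed camera. It also took 1 member from each other list and 16 genes always reported, of which Alas2 was not among the tested genes. Predicted genes and olfactory receptors were left out of the names. The pancreatic enzyme genes, Reg1, Reg2, Reg3a, Arntl, Retnlb, Jchain and Ly6g were named after their values were seen, as were the members of gene families and marker panels in the additional observations.

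The alternatives were a mean-variance trend with robust variance, array weights, repeated quantile normalization, equal array medians, leaving out the 33.3% of genes with the lowest mean, the mean of a gene's probe sets, all probe sets, the replicate number as a block, and leaving out each array in turn. Covariates for posterior colon genes and for pancreatic enzyme genes were added after the data were seen. No pair of arrays was identical, and correlations between arrays lay between 0.974 and 0.993. The first principal component held 45.6% of the variance. The genotypes did not overlap on it. Knockout replicate 3 lay at 0.21, between the other knockouts (21.6 to 37.8) and the wild type arrays (-24.6 to -16.1). Its mean correlation was 0.9882 with the wild type arrays and 0.9867 with its own group. For every other array the mean correlation was higher within its own group. Knockout replicate 3 also lacked the signal of pancreatic enzyme genes, so this component cannot tell genotype from that signal.

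The scripts were tested on simulated data made from the real gene means and spreads, with 200 of 22180 genes changed, for knockout against wild type. Limma recovered 42% of 50 genes changed by 0.5 on the log2 scale, 82% of 50 changed by 1, 100% of 50 changed by 2 and 100% of 50 changed by 3, with 9 false calls among the unchanged genes. Data with no changed gene gave 0 calls among genes and 0 among lists. The simulated genes were drawn independently of each other, whereas the correlation estimated in the real MHC class II list was 0.876. The simulation therefore does not show how often camera calls a list of correlated genes.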

Results

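RNA was measured in the middle colon of 8 female mice on a C57BL/6 background, 9 weeks old, after chemically induced colitis. Dextran sulfate sodium (DSS), a polysaccharide that injures the colon epithelium, was added to the drinking water at 4% for 7 days. Plain water followed for 5 days, and tissue was taken on day 12. 4 mice were wild type and 4 were knockouts without Trim58, a ubiquitin ligase of the tripartite motif family. Each mouse gave 1 whole-transcript array, and the medians of the 8 arrays lay between 5.73 and 5.83 on the log2 scale. The number of arrays limits the precision. All 8 mice received DSS, so the data compare genotypes within colitis and hold no untreated colon.

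Trim58 itself had a low array signal in both genotypes. The wild type replicates 1 to 4 read 5.22, 5.07, 5.18 and 5.03 and the knockout replicates 4.91, 5.37, 4.82 and 5.11 (log2). The wild type mean was 5.12 ± 0.09 and the knockout mean 5.05 ± 0.24 (SD, n = 4 each), a log2 difference of -0.07 with a standard error of 0.12 (limma adjusted p = 0.839; exact two-sided permutation p = 0.6). This probe set therefore did not separate the genotypes and does not check the labels. Whether its probes lie inside the deleted part of the gene is not given in the sources used here. Its mean was at the 28.5 percentile of all tested genes and above 90.8% of 1105 olfactory receptor genes, a class not expected in colon. Signals of different probe sets are not on a common scale, so this rank is only a rough guide to the RNA level.

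The comparison asks how the loss of Trim58 alters gene expression in the DSS-treated colon. Of the gene lists fixed beforehand, 13 of 19 neutrophil markers, 7 of 29 inflammatory cytokine and chemokine genes and 5 of 17 antimicrobial and acute-phase genes were higher in the knockout. A smaller set, with the phosphate transporter gene Slc34a2 and the cytochrome P450 gene Cyp2f2 among the largest differences, was lower. Reg3b and Reg3g, C-type lectins that the gut epithelium secretes against bacteria, showed the largest differences among genes past the test. Reg3b went from 5.68 ± 0.68 in wild type to 11.21 ± 1.52 in knockout (log2, SD, n = 4 each), a 46.2-fold difference with limma adjusted p = 0.00622. Its shift was 3.40 in knockout replicate 3 and 6.24 on average in the other 3 knockouts (log2), the arrays that also carried pancreatic enzyme genes. Reg3g was 22.2-fold higher (log2 difference 4.47 ± 0.52 SE, limma adjusted p = 0.00622). The shift of Reg3g was likewise 2.82 in knockout replicate 3 and 5.03 on average in the other 3 knockouts. From which tissue in the samples the Reg3b and Reg3g RNA came was not tested. Saa3, an acute-phase serum amyloid, was 18.1-fold higher and Il1b, the cytokine interleukin-1 beta, 10.4-fold higher.

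Of 22180 genes tested with limma, 87 were higher and 41 lower in the knockout at a Benjamini-Hochberg adjusted p under 0.05. In all 128 the 4 knockout values lay outside the range of the 4 wild type values. Over all genes 8.81% had no overlap between genotypes, where chance gives 2.86%. Of the genes called higher, 53 differed at least 2-fold and 20 at least 4-fold. Of those called lower, 9 differed at least 2-fold and 1 at least 4-fold. At an unadjusted limma p under 0.05 and at least 1.5-fold, 346 genes were higher and 172 lower. Single arrays moved the adjusted counts strongly. Leaving out wild type replicate 2, 3 or 4 gave 24 higher and 1 lower, 50 and 28, and 56 and 9, and leaving out knockout replicate 1, 2 or 3 gave 46 and 9, 36 and 7, and 172 and 80. With each array's mean of pancreatic enzyme genes or of posterior colon genes as a covariate, both chosen after the data were seen, 2 genes stayed past the threshold, S100a9 and Stfa2l1. Of 36 called genes named, 14 passed in every fit without 1 array, all of them higher, and the others, each named lower gene included, lost their call in at least 2 of these 8 fits.

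**Figure D1:**
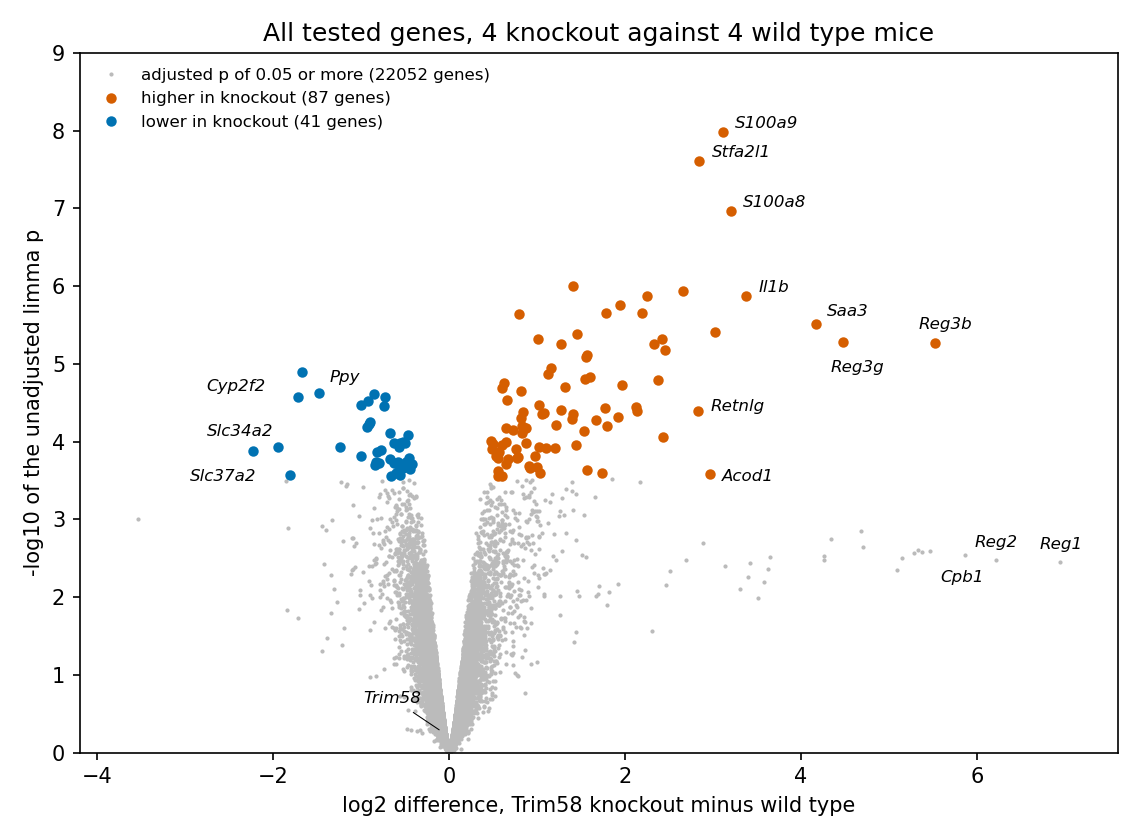
Each point is 1 of the 22180 tested genes, with the log2 difference between Trim58 knockout and wild type on the x axis and -log10 of the unadjusted limma p on the y axis (4 mice per genotype). The 87 genes called higher reach further from 0 than the 41 called lower, and Reg1, Reg2 and Cpb1 lie far to the right without passing the adjusted test.

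The 10 largest increases were completed by S100a8, S100a9, Clec4e, Acod1, Stfa2l1 and Retnlg, genes known from activated neutrophils and other myeloid cells. S100a8 and S100a9, the subunits of calprotectin, were 9.20-fold and 8.64-fold higher (limma adjusted p = 0.000802 and 0.000233). Clec4e, a receptor for microbial glycolipids, was 8.11-fold higher, and Acod1, which makes itaconate, 7.79-fold higher. Stfa2l1 was 7.19-fold and Retnlg 7.09-fold higher. Stfa2l1, Saa3, Reg3b and Reg3g belong to families of similar sequence, so hybridisation of a relative's RNA to their probes is a source of uncertainty.

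The largest decrease was in Slc34a2, a phosphate transporter, which was 4.68-fold lower (log2 difference -2.23 ± 0.37 SE, limma adjusted p = 0.0320) and Slc37a2, a sugar phosphate transporter, 3.50-fold lower (limma adjusted p = 0.0478). The cytochromes P450 Cyp2f2 and Cyp2c68 were 3.30-fold and 2.01-fold lower, and Ppy, which encodes pancreatic polypeptide, 2.78-fold lower. Gsdmc3, a gasdermin, was 2.36-fold lower, the actin-severing protein gene Scin 2.01-fold, the serotonin transporter gene Slc6a4 1.91-fold, Wfdc2 1.88-fold and the clock gene Npas2 1.86-fold. The limma adjusted p of these 8 genes lay between 0.0149 and 0.0358.

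**Figure D2:**
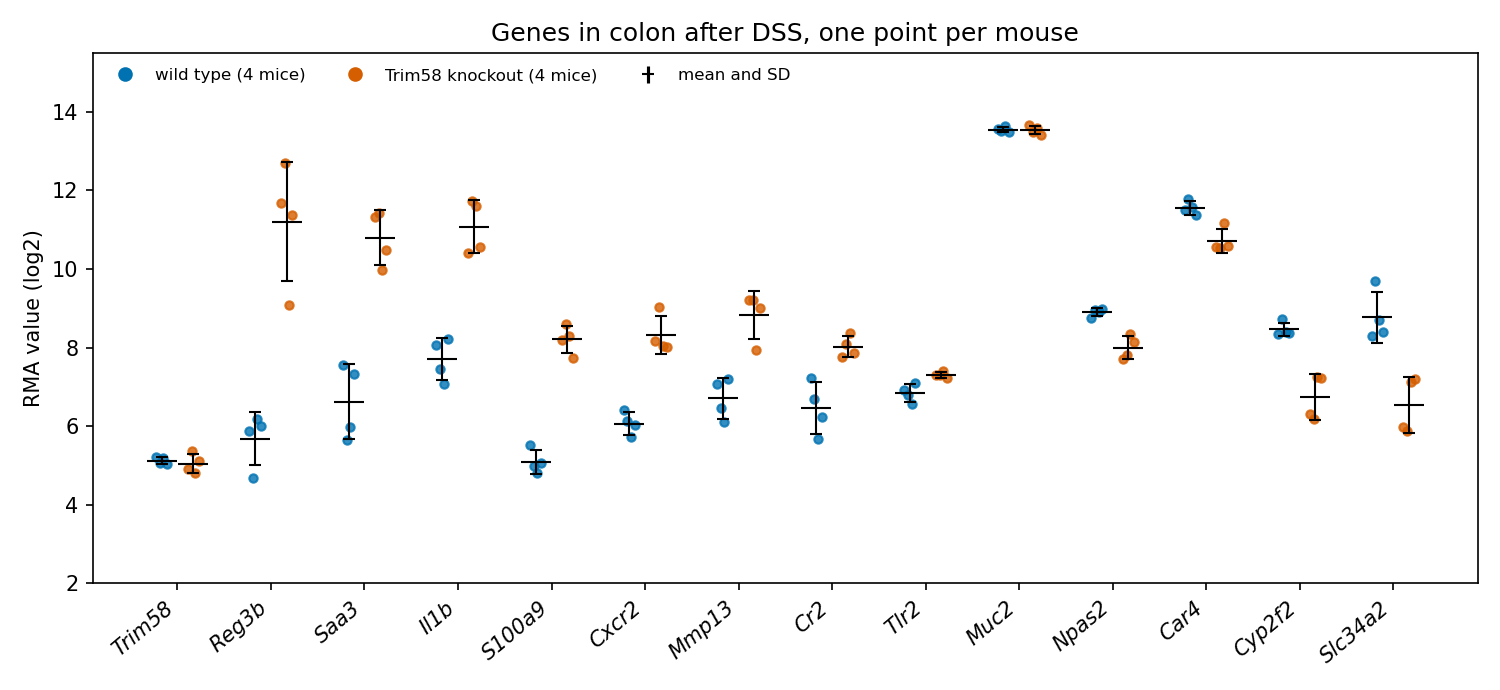
RMA values (log2, y axis) of 14 genes in each of 4 wild type and 4 Trim58 knockout mice, with the mean and SD of each group. Trim58, Muc2 and Tlr2 did not pass the adjusted test. The genotypes overlap for Trim58 and Muc2, and for the other genes, Tlr2 included, the knockout values lie entirely above or below those of the wild type.

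Digestive enzyme genes of the pancreas were present at high level in 3 of the 4 knockout samples. These genes were chosen after their values were seen. All 18 enzyme or secretory genes examined were higher in knockout replicates 1, 2 and 4 than in every other array. The mean of these 3 arrays exceeded that of the other 5 by 2.35 to 7.82 on the log2 scale. Their mean was 10.26, 11.41 and 11.04 in those arrays, 5.36 in knockout replicate 3 and 5.43 to 5.53 in the wild type arrays. Carboxypeptidase B1 (Cpb1) read 12.18, 12.65, 4.62 and 12.50 in knockout replicates 1 to 4 and 4.62 ± 0.07 in wild type (SD, n = 4). None of the 18 passed the adjusted limma test with all arrays, where their adjusted p lay between 0.0907 and 0.312, and all 18 passed it without knockout replicate 3. Reg1, Reg2 and Reg3a, relatives of Reg3b, followed the same arrays. Reg1 was at 2.66 in knockout replicate 3 and at 11.31 to 12.80 in the other 3. In total 38 genes were at least 1 log2 unit above every other array in these 3 arrays, against at most 2 genes for any other set of 3 arrays. Among them were 4 genes called higher, Reg3b, Reg3g, Mmp10 and Mmp13. Of the 346 genes higher at the unadjusted threshold, 47 had knockout replicates 1, 2 and 4 above every wild type value and replicate 3 not.

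**Figure D3:**
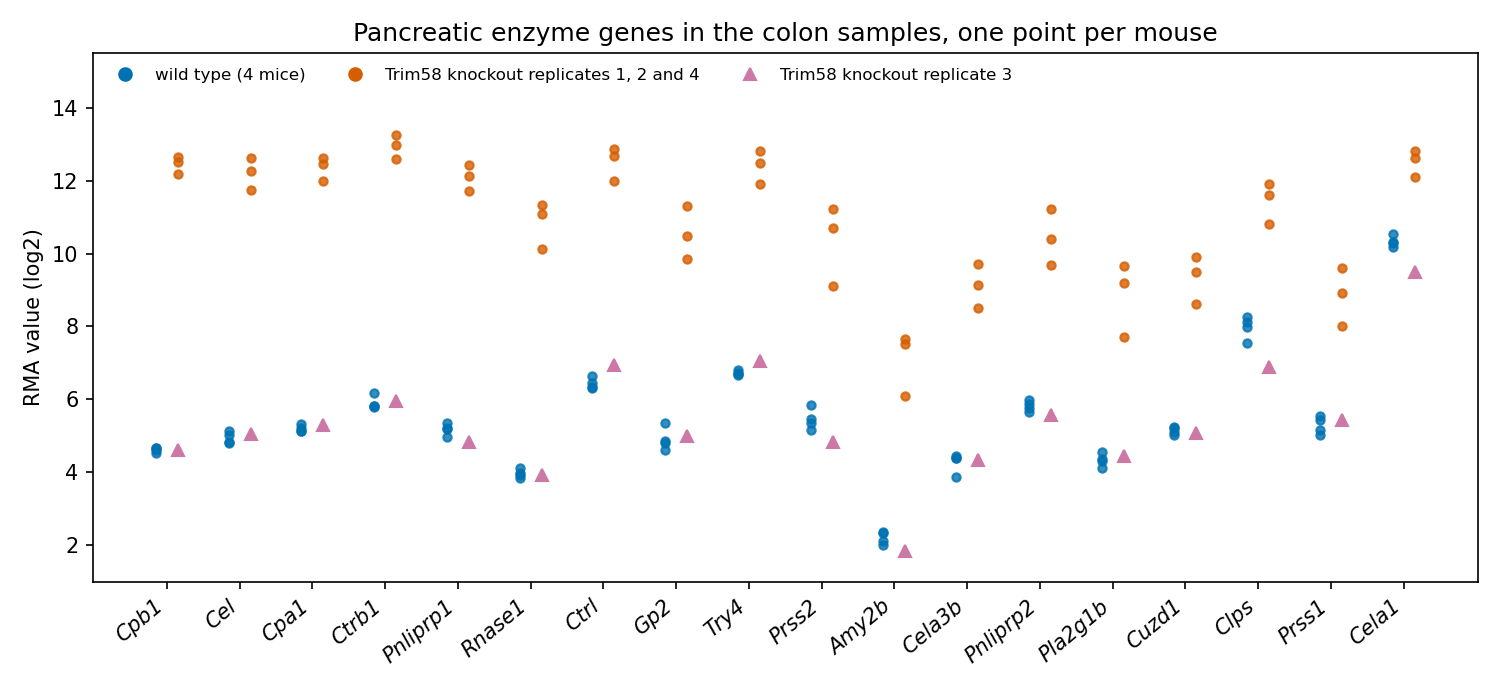
RMA values (log2, y axis) of 18 pancreatic enzyme and secretory genes in each mouse. Knockout replicates 1, 2 and 4 (circles) lie above the wild type for every gene, and knockout replicate 3 (triangles) lies near or below the wild type values.

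Most neutrophil markers were higher. Of 19 measured neutrophil markers, 13 were higher and 0 lower at the adjusted threshold over all genes, and 15 were higher adjusted over the list alone. Their mean was 2.95-fold higher in the knockout (limma camera adjusted p = 9.29e-23; adjusted p = 0.0954 with an estimated correlation). Cxcr2, a chemokine receptor of neutrophils, was 4.75-fold higher. Knockout replicate 3, which lacked the pancreatic signal, had a list mean 1.75 above wild type on the log2 scale, and the other 3 knockouts lay at 1.25, 2.01 and 1.23. Ly6g, a marker named after its value was seen, had a log2 difference of -0.36 (limma adjusted p = 0.621).

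Of 29 inflammatory cytokine and chemokine genes, 7 were higher and 0 lower over all genes, and 17 were higher and 1 lower adjusted over the list alone. The list mean was 1.87-fold higher (camera adjusted p = 3.87e-17; adjusted p = 0.0954 with an estimated correlation). Cxcl5, which attracts neutrophils, was 5.04-fold higher, Ptgs2, the inducible cyclooxygenase, 3.84-fold. Il6 passed the test (limma adjusted p = 0.0229) with a log2 difference of 1.80 (95% interval 1.18 to 2.41). Its wild type mean of 2.97 lay below the median of the olfactory receptor genes (3.26), so this difference may be compressed. The shift of Il6 was 0.98 in knockout replicate 3 and 2.07 on average in the other knockouts. Tnf, Il10 and Cxcl1 did not pass, with log2 differences of 0.41, 0.20 and 0.65 and limma adjusted p of 0.614, 0.343 and 0.0710.

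Among 17 antimicrobial and acute-phase epithelial genes, 5 were higher over all genes and 10 adjusted over the list alone, with none lower. The list mean was 2.79-fold higher (camera adjusted p = 1.30e-08; adjusted p = 0.0954 with an estimated correlation). Lcn2, which binds bacterial siderophores, was 5.35-fold higher. In knockout replicate 3 the list mean was 1.14 above wild type and in the other 3 knockouts 1.59 on average (log2). Reg3b was 9.09 in knockout replicate 3, above the wild type maximum of 6.18, and between 11.38 and 12.69 in the others.

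Matrix and tissue remodelling genes were higher as a list with camera's preset correlation. Of 24 measured, 4 were higher over all genes, 17 were higher adjusted over the list alone and 0 lower, with a mean 1.61-fold higher (camera adjusted p = 3.30e-17; adjusted p = 0.146 with an estimated correlation). The collagenase Mmp13 and the stromelysin Mmp10 were 4.38-fold and 4.35-fold higher, and the membrane-bound protease Mmp14 1.39-fold. The list mean was 0.33 above wild type in knockout replicate 3 and 0.81 in the other knockouts (log2). With the pancreatic covariate it was 0.36 with the call kept.

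Of 20 monocyte and macrophage markers, 3 were higher over all genes and 6 adjusted over the list alone (mean 1.38-fold higher, camera adjusted p = 4.69e-07; adjusted p = 0.356 with an estimated correlation). Chil3, a chitinase-like protein of activated macrophages that neutrophil precursors also make, was 6.34-fold higher. Itgam, an integrin that neutrophils share, was 2.14-fold and the scavenger receptor gene Msr1 2.07-fold higher. Without wild type replicate 3 the list mean went from 0.46 to 0.30 on the log2 scale. Hdc, which makes histamine, was 3.44-fold higher and the single call among 15 mast cell and eosinophil markers (1 adjusted over the list alone, camera adjusted p = 0.104). That list passed without wild type replicate 4 (mean 0.23) and without knockout replicate 1 (0.20) and with the posterior covariate (0.18), and its mean was 0.10 without knockout replicate 2 and 0.07 with the pancreatic covariate.

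The B and plasma cell list held genes in both directions. Of 18 measured, 1 was higher over all genes, and 12 were higher and 2 lower adjusted over the list alone (camera adjusted p = 8.38e-07; adjusted p = 0.375 with an estimated correlation). Cr2, the complement receptor of mature B cells and follicular dendritic cells, was 2.96-fold higher (limma adjusted p = 0.0440). Ms4a1 and Bank1, B cell genes, had log2 differences of 1.44 and 1.33 and missed the threshold (limma adjusted p = 0.0613 and 0.0585). Jchain, which plasma cells express, had a log2 difference of -1.31 (limma adjusted p = 0.159). The 9 measured MHC class II genes all had differences above 0, with 0 calls over all genes and 4 adjusted over the list alone (camera adjusted p = 7.55e-05; adjusted p = 0.375 with an estimated correlation). Of 19 T and NK cell markers, 0 passed over all genes and 2 adjusted over the list alone, the granzyme genes Gzma and Gzmb with log2 differences of 1.17 and 1.09 (camera adjusted p = 0.00818; adjusted p = 0.453 with an estimated correlation). Without wild type replicate 3 the B and plasma cell mean went from 0.49 to 0.28 and the MHC class II mean from 0.42 to 0.26. The T and NK cell call ended without wild type replicate 3 (mean 0.10) and without knockout replicate 3 (0.15), and its mean was 0.34 with the pancreatic covariate.

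The colonocyte, goblet cell and enteroendocrine lists passed the camera test downwards. Of 20 absorptive colonocyte genes, 2 were lower over all genes, Slc37a2 and the carbonic anhydrase gene Car4 (1.80-fold), and 4 were lower adjusted over the list alone (mean log2 difference -0.31, camera adjusted p = 0.000110; adjusted p = 0.0954 with an estimated correlation). The water channel gene Aqp8 had a log2 difference of -1.16 and missed the threshold (limma adjusted p = 0.0543). Of 18 goblet cell genes, 1 was lower over all genes, the protease gene Capn9 (log2 difference -0.49), while 7 were lower and 1 higher adjusted over the list alone (camera adjusted p = 1.00e-04; adjusted p = 0.375 with an estimated correlation). Retnlb opposed the list with a log2 difference of 2.51 (limma adjusted p = 0.134), and Muc2, the main colonic mucin, had a difference of -0.01. The goblet list mean was 0.00 in knockout replicate 3 and -0.15 in the other knockouts. It was -0.11 over all 4, turned to 0.0379 with the pancreatic covariate, where the call ended, and was -0.30 with the posterior covariate. Without wild type replicate 3 and knockout replicates 1, 2 and 4 in turn it was -0.05, -0.19, -0.07 and -0.04. Of 16 enteroendocrine and tuft cell genes, 0 passed over all genes and 4 were lower adjusted over the list alone (camera adjusted p = 0.00818; adjusted p = 0.325 with an estimated correlation). The hormone genes Insl5 and Pyy had log2 differences of -1.17 and -0.87 (limma adjusted p = 0.0564 and 0.0797). The enteroendocrine call ended without wild type replicate 3 (mean -0.28, camera adjusted p = 0.0507) and with the posterior covariate (-0.18).

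Proliferation genes were higher as a list (24 measured, 0 over all genes and 6 higher adjusted over the list alone, mean 1.14-fold, camera adjusted p = 2.77e-07; adjusted p = 0.0954 with an estimated correlation), with Rrm2 at a log2 difference of 0.46 and Mki67 at 0.23. The list mean went from 0.19 to 0.12 with the posterior covariate. Mitochondrial fatty acid oxidation genes were lower as a list, with all 19 below 0 and 0 passing over all genes or adjusted over the list alone (mean log2 difference -0.19, camera adjusted p = 2.43e-05; adjusted p = 0.146 with an estimated correlation). The 18 smooth muscle genes averaged -0.33 with 0 calls either over all genes or adjusted over the list alone (camera adjusted p = 2.87e-06; adjusted p = 0.387 with an estimated correlation), at -0.51 in knockout replicate 3, -0.27 in the others and -0.21 with the posterior covariate. Enteric neuron and glia genes averaged -0.13, with 0 calls over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.0389; adjusted p = 0.413 with an estimated correlation). This call ended without wild type replicate 4 (mean -0.08), without knockout replicate 3 (-0.10) and with the posterior covariate (-0.05), and the mean was -0.23 with the pancreatic covariate. Endothelial genes averaged 0.14 with 0 calls over all genes or adjusted over the list alone (camera adjusted p = 0.00566; adjusted p = 0.410 with an estimated correlation), at -0.05 in knockout replicate 3 and 0.21 in the others. The endothelial call ended without wild type replicate 3 (mean 0.07, camera adjusted p = 0.125) and turned with the pancreatic covariate (-0.0349). Posterior colon position genes, Hox genes that mark the distal gut, averaged -0.28 with 0 calls over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.00427, or 0.173 with an estimated correlation). Relative to the wild type mean, this list stood at -0.47, -0.45, -0.22 and 0.0006 in knockout replicates 1 to 4 (exact two-sided permutation p = 0.0857). Knockout replicate 4 thus lay at the wild type level. Hoxb13, the list member with the smallest p, had a log2 difference of -0.91 and did not pass (limma adjusted p = 0.124).

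Of 22 measured TLR2 signalling genes, 14 had differences above 0 and 8 below, and 0 passed over all genes and 2 were higher adjusted over the list alone, with a mean 1.06-fold higher (camera adjusted p = 0.0309; adjusted p = 0.393 with an estimated correlation). The list call ended without wild type replicate 3 (mean 0.05), knockout replicate 2 (0.07) or knockout replicate 3 (0.07), where the mean over all arrays was 0.09, and the mean was 0.14 with the pancreatic covariate. Tlr2 went from 6.83 ± 0.23 to 7.31 ± 0.08 (log2, SD, n = 4 each), a 1.39-fold difference with no overlap that missed the threshold (limma adjusted p = 0.0924). Tlr1, Tlr6 and Myd88 had log2 differences of -0.02, 0.31 and 0.17 and did not pass. Unfolded protein response genes averaged 0.08 with 0 calls over all genes or adjusted over the list alone (camera adjusted p = 0.0385; adjusted p = 0.413 with an estimated correlation). That call ended without wild type replicate 3 (mean 0.08), wild type replicate 4 (0.05) or knockout replicate 3 (0.05), and the mean was 0.15 with the pancreatic covariate.

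**Figure D4:**
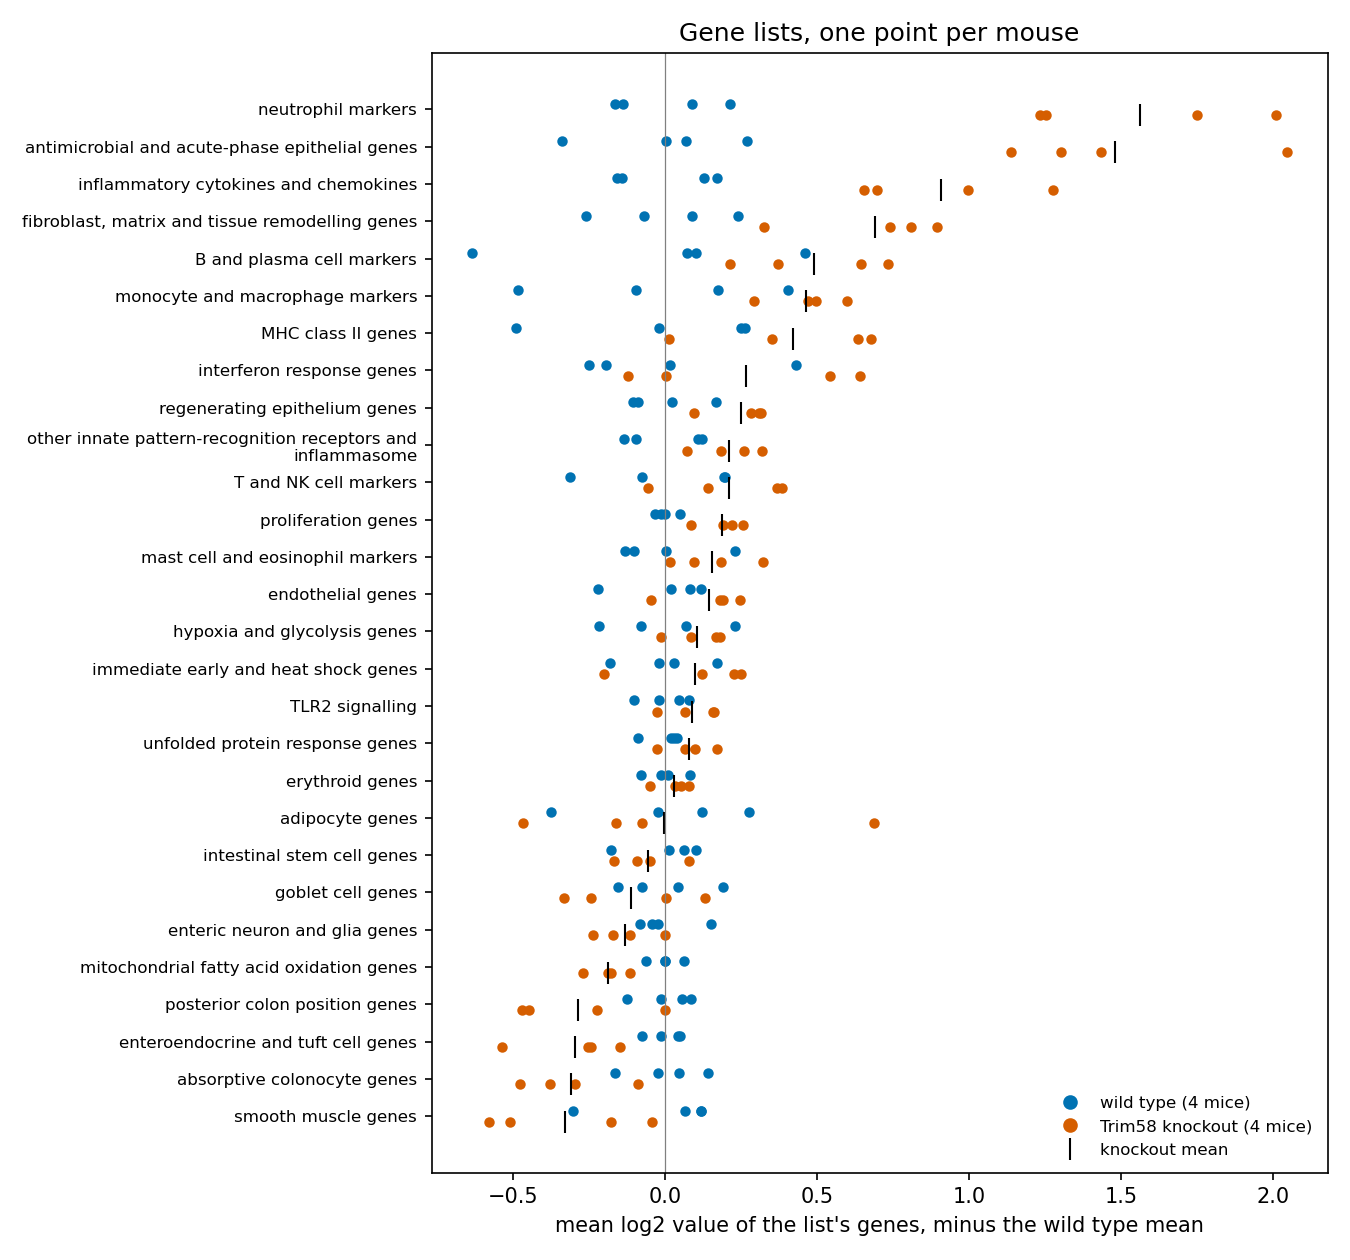
Mean log2 value of each of the 28 gene lists in each mouse, relative to the wild type mean (x axis), with the knockout mean as a bar. The neutrophil, antimicrobial, cytokine and matrix lists have all 4 knockout mice above all 4 wild type mice, and the smooth muscle and colonocyte lists have the lowest knockout means.

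Besides the mast cell and eosinophil list, 8 lists did not pass the camera test, and none of the 8 held a gene past the threshold over all genes. Camera adjusted p was 0.0508 for other pattern-recognition receptors and inflammasome genes (4 higher and 1 lower adjusted over the list alone) and 0.0508 for interferon response genes (3 higher adjusted over the list alone). It was 0.0639 for regenerating epithelium genes (4 higher adjusted over the list alone), 0.198 for intestinal stem cell genes and 0.0980 for hypoxia and glycolysis genes (0 each adjusted over the list alone). It was 0.215 for immediate early and heat shock genes (2 higher adjusted over the list alone), 0.405 for erythroid genes (2 higher adjusted over the list alone) and 0.869 for adipocyte genes (0 adjusted over the list alone). Several passed without single arrays. The pattern-recognition list did without wild type replicate 1 (mean 0.25), wild type replicate 4 (0.25) and knockout replicate 1 (0.25), where it was 0.21 over all arrays. The interferon list, at 0.27 over all arrays, passed without wild type replicate 1 (0.41) and knockout replicates 1 (0.40) and 4 (0.35), and was at 0.17 and 0.14 without knockout replicates 2 and 3. Knockout replicate 3 stood at 0.64 in this list and the other knockouts averaged 0.14. The regenerating epithelium list did without wild type replicate 4 (0.31) and knockout replicates 2 (0.23) and 3 (0.30), from 0.25 over all arrays. The stem cell list, at -0.06, passed without wild type replicate 4 (-0.12) and knockout replicate 1 (-0.10), and was at -0.04, -0.02 and -0.02 without wild type replicates 1 and 3 and knockout replicate 4. The hypoxia list, at 0.10, passed without wild type replicate 1 (0.18) and knockout replicate 1 (0.14), and was at 0.03 without wild type replicate 4. The immediate early list, also at 0.10, passed without wild type replicate 4 (0.16) and knockout replicate 1 (0.20), and was at 0.04, 0.06 and 0.05 without wild type replicate 3 and knockout replicates 2 and 3. The erythroid mean lay between 0.00 and 0.06 without single arrays. With the posterior covariate the pattern-recognition (0.26), interferon (0.24), regenerating epithelium (0.265), stem cell (-0.18), immediate early (0.23) and adipocyte (0.31) lists passed. With the pancreatic covariate the pattern-recognition (0.30), interferon (0.565), immediate early (0.20) and adipocyte (-0.45) lists did. The regenerating epithelium (0.10), stem cell (-0.03) and hypoxia (0.16) lists did not pass with it. The erythroid median was -0.0022 and the mean 0.03, and the adipocyte median was -0.02 and the mean -0.01 where its test pointed up. The stem cell gene Lgr5 had a log2 difference of -0.20 (limma adjusted p = 0.766). In all, 12 lists were higher and 7 lower with camera's preset correlation, 0 passed with an estimated correlation (8 at an unadjusted p under 0.05), 7 passed limma's fry test for movement in 1 direction and 18 its test for movement in either. The list means of 7 lists reached the smallest exact two-sided permutation p that 4 against 4 mice allow, 0.0286 (0.114 after Benjamini-Hochberg adjustment over 28 lists).

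Genes beside Trim58 were examined for effects tied to the targeted locus. Of 68 measured genes within 1 Mb in the reference gene table (GRCm38.p6, used for neighbours alone), 8 had an unadjusted limma p under 0.05, 3 higher and 5 lower, and 0 passed the adjusted test. That is 11.8% of these genes, against 14.3% of all tested genes. Nlrp3, the inflammasome sensor, had the smallest p among them, with a log2 difference of 0.90 (limma adjusted p = 0.0792).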

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

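The tests of pancreatic tissue, of array order, of other splits for the gene counts and of what ended the calls were chosen after the results they bear on were seen; both covariates were added after the data were seen, and the bounds for colon position were written before that covariate was run.

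A knockout sample stood apart from its group in 5 pancreatic genes. Knockout replicate 3 was at 4.62 for Cpb1, 5.29 for Cpa1, 5.94 for Ctrb1, 2.66 for Reg1 and 2.92 for Reg2 (log2), where the lowest of the other 3 knockouts read 12.18, 11.98, 12.59, 11.31 and 10.70. It also stood apart with the highest Car4 of its group, 11.18 against 10.54 to 10.58, and with a regenerating epithelium list mean of 0.0935 against 0.28 to 0.32. Single samples far from their group were also Cxcr2 in knockout replicate 2 (9.03), Top2a and Mki67 in knockout replicate 4 (8.70 and 9.51), Il10 in knockout replicate 1 (3.94), Chga in knockout replicate 2 (7.78), Cyp2f2 in wild type replicate 2 (8.73) and Ctrb1 in wild type replicate 3 (6.17). The smooth muscle list mean in wild type replicate 3 (-0.30) and the unfolded protein response list mean in wild type replicate 4 (-0.0897) completed them. In total 16 of 256 groups held such a sample, where chance gives about 12.8. The 5 pancreatic genes were named after their values were seen and add to the count by choice, so it shows no excess over chance.

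Among probe sets left out of the comparison, 1 of 16010 without a gene symbol was lower in the knockout and 1 of 1814 with several symbols was higher at a limma adjusted p under 0.05, each adjusted within its own class.

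Pancreatic enzyme genes were high in 3 of 4 knockout samples, and pancreatic tissue carried along with the colon piece is a candidate source. Of 10 further genes known from acinar cells, 5 were above every other array in the same 3 arrays, exactly the number the test required, among them the acinar transcription factors Ptf1a and Rbpjl, while others such as Klk1 and Spink1 were already above 11 on the log2 scale in the wild type colon. Ins2, the insulin gene abundant in islets, was at 3.92, 4.09 and 4.07 in those arrays and at most 3.82 in the others, a small gap at a low level. The other islet genes examined, such as Iapp, Pdx1 and Gcg, were not above every other array there. Ppy was below the wild type in all 4 knockouts, at 7.68 in knockout replicate 3 against a lowest wild type value of 8.55. Acinar genes switched on in the knockout colon itself were not tested and stay open, as does the question of why no wild type sample carried the signal.

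Pancreatic tissue as a source of the other called genes was weighed next. Of the 172 genes called higher without knockout replicate 3, 24 were pancreatic panel genes or Reg1, Reg2 and Reg3a; over the other 148 its shift was a median of 0.563 times that of the other knockouts (quartiles 0.297 and 0.842), and 26 did not exceed the wild type range there. Over the 43 of the 172 that belong to the lists fixed beforehand the median was 0.777 (quartiles 0.504 and 1.04), and 2 did not exceed that range. Over all 172 it was 0.512. For knockout replicates 1, 2 and 4, each left out of the choice of genes in turn, it was 0.832, 1.39 and 0.782. Those medians cover the 46, 36 and 66 genes called higher without the array in question. Since a single array lacks the signal, how far pancreatic tissue accounts for the higher genes cannot be told apart from genotype. The 41 lower genes had a median of -0.73 (upper quartile -0.57) where 10 pan-epithelial genes had -0.12 (lower quartile -0.21). This argues only weakly against dilution by pancreatic RNA as their whole cause. The 41 were picked for passing the test, which favours large differences, and the bright panel may be compressed. Over 80 genes called lower without knockout replicate 3, its shift was a median of 0.547 times that of the other knockouts. With replicates 1, 2 and 4 left out in turn it was 0.680, 1.46 and 0.5025 over 9, 7 and 36 genes. Replicate 4 carries the enzyme signal, so these ratios do not settle the cause.

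With posterior colon genes as a covariate the log2 differences kept a median of 0.897 of their size over the 87 higher genes (quartiles 0.851 and 1.00). This argues against colon position as their whole cause only so far as the covariate records position. The covariate is the mean of 8 genes, was correlated with genotype at -0.70 and may remove only part of a position effect. Over the 41 lower genes the median was 0.813. The bound set beforehand was a median above 0.8 with quartiles above 0.5; the lower genes meet it by less than their spread, so position stays open for them. The labels list the wild type mice as 1 run before the knockouts, with 1 change of genotype along the order, so order and genotype cannot be told apart.

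Both covariates ended nearly all calls, mostly through wider errors. Of 128 called genes, 63 stayed past the threshold with the differences from the posterior covariate and the original errors, 6 with the original differences and the new errors, and 2 with both. For the pancreatic covariate these were 78, 12 and 2. Over the 87 higher genes the median log2 difference went from 1.20 with a standard error of 0.18 to 0.98 with 0.24 for the pancreatic genes, and the standard error was 0.24 for colon position as well. Over the 41 lower genes it went from -0.73 with 0.12 to -0.62 with 0.18 for the pancreatic genes and to -0.58 with 0.16 for colon position. All 128 genes had an unadjusted limma p under 0.05 and the same sign with either covariate.

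Chance in how the 8 arrays were divided was tested over all 35 splits into 4 and 4. For the 87 higher genes 1 split, the real one, gave as many and the highest other gave 0; for the 41 lower genes it was again 1 split and the highest other gave 1. For the unadjusted 1.5-fold counts, 1 split reached 346 higher (highest other 202) and 1 reached 172 lower (highest other 128). The real split gave the largest of each of these counts, the most that 35 splits can show. The tests were chosen after the counts were seen, and splits that mix the genotypes carry a genotype difference as spread. Chance is therefore not excluded by them. Nor can it be excluded for the gene lists, where 5 of the 35 splits gave at least 19 lists and the highest other gave 21. The other 4 of these splits each kept 3 knockouts together. The median over the splits other than the real one was 9 lists, and splits with 2 knockouts on each side, which hold no genotype contrast, gave up to 16. For the genes within 1 Mb of Trim58, 1 split gave 8 and the highest other 7.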

How the results depend on the processing

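The covariates for posterior colon genes and pancreatic enzyme genes were chosen after the data were seen. All 87 higher and 41 lower genes kept their direction in every fit that tested them, but their number past the threshold varied. The sign could not turn without 1 array or with array weights, since the genotypes did not overlap in any of these genes. The variance trend and the replicate block leave the difference itself unchanged. Lower genes numbered 64 with a variance trend, 69 with array weights and 80 without the 33.3% of genes with the lowest mean, where fewer genes were tested. Testing all probe sets, which adds tests, gave 24 higher and 1 lower, and 550 and 323 at an unadjusted p under 0.05 and 1.5-fold. Each of the 2 covariates left 2 higher and 0 lower. Replicate numbers did not pair the samples: correlations of deviations between same-numbered arrays lay between -0.16 and 0.05, and 0 of 8 arrays matched its own number best. The replicate block gave 56 higher and 8 lower.

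Leaving out each array in turn gave 24 to 172 higher and 1 to 80 lower genes, 275 to 440 higher and 119 to 246 lower at the unadjusted threshold, 14 to 25 lists and 4 to 9 genes near Trim58, the 4 without wild type replicate 2. The adjusted counts were 24 and 1 without wild type replicate 2, 50 and 28 without wild type replicate 3, 56 and 9 without wild type replicate 4, 46 and 9 without knockout replicate 1, 36 and 7 without knockout replicate 2 and 172 and 80 without knockout replicate 3. The Trim58 difference ranged from -0.18 to 0.00285, its sign turning without knockout replicate 3. Near Trim58, 500 kb held 5 genes and 2 Mb held 13, in line with the number of genes covered (43 and 93).

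Of 28 lists, 0 passed camera with an estimated correlation and 7 fry. The other settings with all 8 arrays gave 17 to 23 lists. Differences near 0 changed sign: Tlr1 (0.00163 with repeated quantile normalization, 0.00876 and 0.0856 with the posterior and pancreatic covariates, -0.0651 to 0.0360 without single arrays) and Muc2 (0.0578 with the pancreatic covariate, -0.0526 to 0.0308 without single arrays). The adipocyte list read 0.0915 with array weights, 0.31 with the posterior covariate and -0.24 to 0.15 without single arrays. With the pancreatic covariate the goblet cell list turned to 0.0379 and the endothelial list to -0.0349; the cause was not tested for these. Of 36 called genes named, 0 reversed, which many of these settings could not have produced, and 2 kept their call in every setting. Trim58 and other dim genes have no value where genes of lowest mean were left out.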

Other observations

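The tests of symbol families and of T cell genes were chosen after the values were seen.

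Among genes sharing a symbol root, 271 roots with at least 10 measured members were tested for an excess of calls (Fisher's exact test, 1-sided, Benjamini-Hochberg adjusted). Matrix metalloproteinases led the higher genes, with 6 of 22 called (adjusted p = 5.88e-08), Mmp7, Mmp8, Mmp9, Mmp10, Mmp13 and Mmp14. Of these, Mmp14 lost its call in 6 of the 8 fits without 1 array, and Mmp10 and Mmp13 in 3 each. Mmp10 and Mmp13 were also among the 38 genes that set knockout replicates 1, 2 and 4 apart. Interleukin and interleukin receptor genes followed with 7 of 78 (adjusted p = 3.19e-06), among them Il1a, Il1f9, Il11 and the decoy receptors Il1r2 and Il13ra2. Il6, also in this family, lost its call in 5 of the 8 fits. Cytochromes P450 led the lower genes, with 4 of 98 called (adjusted p = 0.00867), Cyp2c68, Cyp2d22, Cyp2f2 and Cyp2s1. The count of cytochromes also depends on single arrays. Cyp2c68 lost its call in 5 and Cyp2f2 in 2 of the 8 fits without 1 array, and without wild type replicate 2 only 1 gene was called lower.

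Of the B and plasma cell list 1 of 18 genes passed, and its call ended with an estimated correlation (adjusted p = 0.375); for its shift, lymphoid follicles inside more of the knockout pieces are a candidate explanation. Of 8 measured follicle and T zone genes outside the list, 7 were above 0 with a median log2 difference of 0.61, led by Cxcl13 (1.25, limma adjusted p = 0.0788) and Fcrl1 (0.97, limma adjusted p = 0.0576). Ccr7 stood at 0.18 and Lef1 at -0.18. B cells themselves express some of the panel, such as Fcrl1 and Cd37 (0.72), so it cannot separate follicles from B cells alone. A general gain of lymphocytes as the whole cause is argued against by the 19 T and NK cell markers, whose median was 0.0835 (upper quartile 0.335) against 0.57 for the B and plasma cell list, although Gzma (1.17), Gzmb (1.09) and Cd2 (0.54) went with it. Whether follicles grew in the knockout or were cut into the piece by chance stays open, since the arrays hold no histology. The list means of knockout replicates 1 to 4 were 0.21, 0.64, 0.73 and 0.37, those of the wild type 0.46, 0.10, -0.63 and 0.07, and the difference of 0.49 was 0.28 without wild type replicate 3.

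Arntl, the core clock gene, was lower together with Npas2, its partner's relative (log2 differences of -0.74 and -0.90, limma adjusted p = 0.0180 and 0.0220, 4 of 4 knockouts below all wild types). Sampling at another time of day could lower both and raise clock genes of the opposite phase: 7 of 9 measured were above 0, but their median of 0.13 fell between the bounds set beforehand, with Per1 (0.35) and Ciart (0.19) above all wild types in 4 of 4 knockouts and Nr1d1 at -0.52. In the phase of Arntl itself, Nfil3 stood at 0.51 with 4 of 4 knockouts above all wild types and Clock at 0.03, against a shared shift, while Cry1 stood at -0.33, so time of day stays undecided. A lower share of epithelial cells as the whole cause is argued against, since 10 pan-epithelial genes had a median of -0.12. This holds only weakly, since Arntl and Npas2 were picked from the called genes and the bright panel may be compressed. Only 1 of these 10 was above 0, and Epcam, Elf3 and Cldn3 lay below all wild types in 4 of 4 knockouts, so a smaller loss stays open.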
